A study of Mus musculus with 37 samples.

How the data were processed

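Colon RNA of 37 mice was hybridized to Affymetrix Mouse Gene 1.0 ST arrays, as biotin-labelled single-stranded DNA made from snap frozen colon, with 1 array per animal. The deposited values are log2 signals per transcript cluster, produced by the authors with the robust multi-array average (RMA) per the submitters' processing notes, which state no version and no probe filter. The base of the logarithm is not stated and was read as 2 from the usual output of RMA and from the range of the values, 3.03 to 14.96. Arrays carry no count of molecules, so their number per group, 3 to 6, is what limits precision.

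The table held 35511 transcript clusters. A probe annotation listed 23410 of them, 21789 with 1 gene symbol and 1621 with several, and 12101 were not listed. Clusters with 1 symbol were used, and for the 999 genes with several clusters the cluster with the highest mean over all arrays was kept, which left 19938 genes. The probe annotation and the mouse gene table (assembly GRCm38.p6) served only for names and neighbours. The lowest mean correlation of an array with its own group was 0.951, and no array was left out.

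Groups followed genotype, phase and treatment as the sample labels give them. Replicates were taken as separate animals because each title carries an animal number that occurs once. These numbers fall into 4 series, which were treated as possible batches, since the labels give no date or batch. All wild-type acute mice and knockout acute DSS replicates 1 to 3 had plain numbers. The knockout acute controls and knockout acute DSS replicates 4 to 6 formed series 2. All wild-type chronic DSS mice and wild-type chronic controls 1 to 3 formed series 3, and all knockout chronic mice with wild-type chronic controls 4 and 5 series 4.

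All 37 arrays entered 1 linear model with a mean for each of 8 groups (limma 3.58.1 in R 4.3.3, default empirical Bayes, 29 residual and 3.18 prior degrees of freedom). The 12 comparisons were DSS against control in each genotype and phase, knockout against wild type in each treatment and phase, the genotype by DSS interaction in each phase, and the chronic against the acute DSS effect in each genotype. P values were adjusted by the Benjamini-Hochberg method within a comparison, and genes passed at an adjusted p under 0.05. All p values are two-sided.

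Gene lists, 37 in number with 678 symbols of which 633 were measured, were written before the data were examined, as were the comparisons, the tests and the alternatives unless said otherwise. Lists with at least 4 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes, and again with the correlation estimated per list. Each list was also given as the number of members that passed, over all genes and adjusted over the list alone. List scores are the mean log2 signal of a list's members in an array, compared by exact permutation of the arrays.

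The genes named were chosen by a rule set in advance. It took the 10 largest positive and the 10 largest negative log2 differences among genes that passed in a comparison, the 3 members of each named list with the largest absolute difference, and Timp1 to Timp4. Predicted genes without an established symbol and clusters of several genes were counted and not named. Exceptions chosen after their values were seen are marked as such.

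The alternatives tried were a trended and robust prior, leaving out the dimmest genes (33.33% with the lowest mean), testing all clusters separately, cyclic loess normalization of the deposited values, array weights, animal series as a covariate, 1 animal series alone, sex as a covariate, only the arrays of the groups compared, and leaving out each array in turn. Sex was read from Xist and Y-linked genes, since the labels do not state it. Leaving out the 2 arrays with Y-linked signal was added after the data were seen.

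The model was tested on simulated data with the same group sizes. For knockout against wild type under acute DSS, 82.1%, 91.0% and 98.5% of genes with simulated differences of 0.5, 1 and 2 log2 units were recovered, and 6.22% of the calls were false. For the acute interaction the recovered shares were 40.3%, 85.1% and 98.5%. Of 10 lists shifted by 0.5, 10 were called at the preset and 10 at the estimated correlation, with 0 of the unshifted lists. The simulated genes varied independently, so lists of correlated genes were not simulated. Each simulated gene had the same SD in all 8 groups and no effect of animal series. The real groups differed in spread, with Timp1 SDs of 0.12 in wild-type acute controls and 1.04 in wild-type acute DSS. The simulated share of false calls therefore need not hold for the real comparisons.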

Results

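Colon RNA from 37 mice was measured on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per animal. The animals were C57BL/6J wild types and B6.129S4-Timp1tm1Pds/J knockouts, which carry a targeted allele of Timp1, the tissue inhibitor of metalloproteinases 1. Colitis was induced with dextran sodium sulphate (DSS) given by mouth, a polysaccharide that damages the colonic epithelium, in an acute and in a chronic protocol, each with its own controls. The acute phase held 3 wild-type controls, 5 wild-type mice on DSS, 3 knockout controls and 6 knockout mice on DSS. The chronic phase held 5 mice in each of its 4 groups. Expression is given as log2 signal, and differences between groups are log2 differences ± the standard error (SE) of limma's fit over 19938 genes. The number of arrays limits the precision of every value. The array medians lay between 7.67 and 7.76, and the first 2 principal components held 38.7% and 14.8% of the variance.

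The first question was whether Timp1 itself followed the genotype and the colitis. In wild-type colon, Timp1 rose 3.12 ± 0.39 log2 units in acute DSS (adjusted p = 5.32e-07, n = 3 and 5) and 1.28 ± 0.34 in chronic DSS (adjusted p = 0.01, n = 5 and 5). Its mean signal was 7.62 ± 0.12 (SD, n = 3) in wild-type acute controls and 10.75 ± 1.04 (SD, n = 5) in wild-type acute DSS. In the knockout the signal was 7.01 ± 0.10 (SD, n = 3) in acute controls and 7.61 ± 0.57 (SD, n = 6) in acute DSS, and the difference of 0.60 ± 0.38 did not pass the test (adjusted p = 0.449). The chronic knockout groups had means of 7.14 ± 0.29 and 7.03 ± 0.19 (SD, n = 5 each). Under acute DSS, Timp1 was lower in knockout by -3.14 ± 0.33 (adjusted p = 1.34e-07, n = 6 and 5), and under chronic DSS by -1.38 ± 0.34 (adjusted p = 0.0255, n = 5 and 5). No genotype difference in Timp1 passed in acute controls (-0.62 ± 0.44, adjusted p = 0.608) or chronic controls (0.01 ± 0.34, adjusted p = 0.996). In acute controls all 3 knockout arrays (6.94 to 7.12) nevertheless lay below all 3 wild-type arrays (7.56 to 7.76). The SE rests on 1 variance for all 8 groups, including wild-type acute DSS with its SD of 1.04. These 2 control groups also came from different series of animal numbers. The test of the difference between the genotypes' responses passed in the acute phase (-2.52 ± 0.55, adjusted p = 0.00468) and not in the chronic phase (-1.39 ± 0.48, adjusted p = 0.157). The labels do not say whether the allele removes the part of the transcript that the array probes. The chronic DSS genotypes came from different series of animal numbers, and with that series in the model the difference of -1.33 had an adjusted p of 0.579. Its call also ended without any one of 6 arrays, with an adjusted p of 0.111 without wild-type chronic DSS replicate 3.

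**Figure D1:**
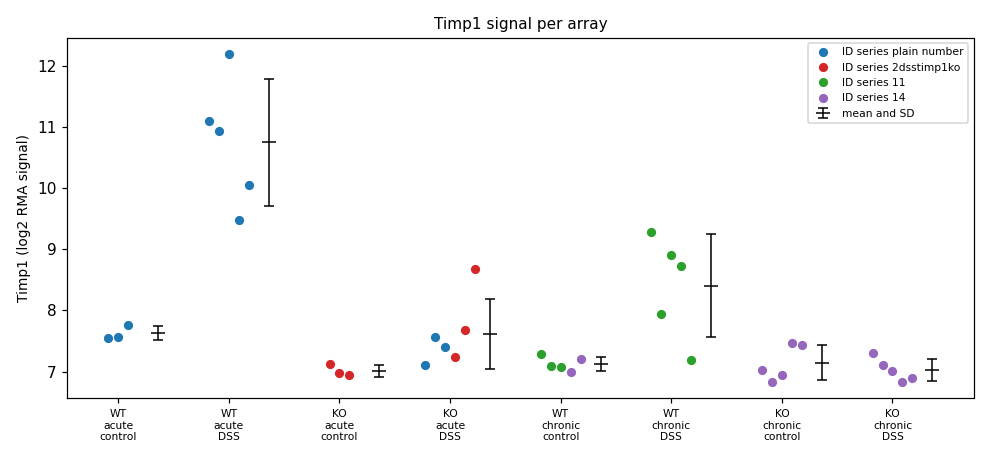
Timp1 log2 signal of each array by group, with the group mean and SD and the series of animal numbers in colour. The wild-type acute DSS arrays ranged from 9.47 to 12.19, and the knockout acute DSS arrays from 7.10 to 8.68.

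The effect of acute DSS in wild-type mice was asked first without the genotype. Wild-type colon gained transcripts of neutrophils, cytokines, proteases and matrix, and lost transcripts of mature colonocytes. Saa3, an acute-phase serum amyloid, rose 6.28 ± 0.72 (77.8-fold, adjusted p = 1.34e-07), and the antibacterial lectins Reg3g and Reg3b rose 5.28 ± 1.09 and 5.26 ± 1.25 (n = 3 and 5). Haptoglobin (Hp) rose 4.65 ± 0.55 and the siderophore-binding Lcn2 rose 4.52 ± 0.75. Cxcl2, which attracts neutrophils, rose 4.33 ± 0.58, the neutrophil-expressed Retnlg 4.21 ± 0.48, and the calprotectin subunit S100a8 4.06 ± 0.62. The collagenase Mmp13 rose 4.12 ± 0.71 and the stromelysin Mmp10 rose 3.95 ± 0.63. The deepest loss was of mucosal pentraxin, Mptx1, at -7.29 ± 1.06 (adjusted p = 3.64e-06). The transglutaminase Tgm3 (-5.42 ± 1.05), the colonic proton-potassium pump Atp12a (-4.53 ± 0.92) and the posterior homeobox gene Hoxb13 (-4.24 ± 0.90) also fell. So did the secretory lectin Reg4 (-3.86 ± 0.60), the sugar-phosphate transporter Slc37a2 (-3.84 ± 0.60), the cytochromes Cyp2c68 (-3.83 ± 0.71) and Cyp2d12 (-3.61 ± 0.53), cathepsin E (Ctse, -3.82 ± 0.61) and syncollin (Sycn, -3.79 ± 0.53).

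Of the 37 gene lists, those of matrix, proteases, myofibroblasts and endothelium moved upward in wild-type acute DSS. Among 29 measured collagen and matrix genes, 25 rose, 0 fell and 4 did not pass (27 rose when adjusted over the list alone). The collagen cross-linking enzyme Lox rose 2.91 ± 0.51, and the basement membrane collagens Col18a1 and Col4a1 rose 2.50 ± 0.29 and 1.78 ± 0.24. Of 25 metalloproteinases and ADAM proteases, 19 rose and 6 did not pass, with 19 higher and 1 lower when adjusted over the list alone. Of 19 myofibroblast and TGF-beta response genes, 12 rose, among them the cytokine Il11 (2.75 ± 0.37), the activin subunit Inhba (2.74 ± 0.34) and the BMP antagonist Grem1 (1.93 ± 0.46), and also 12 when adjusted over the list alone. Of 14 endothelial genes 10 rose, including the endothelial cadherin Cdh5 (1.42 ± 0.30). The matrix, protease and myofibroblast lists were called upward by limma's camera (adjusted p = 6.40e-12, 1.34e-09 and 3.48e-05), none of which held with the correlation estimated per list (adjusted p = 0.496 with an estimated correlation for each of these 3). The endothelial list was called as well (adjusted p = 4.68e-04, and 0.598 with an estimated correlation). The smooth muscle list was not (adjusted p = 0.575, and 0.931 with an estimated correlation), and of its 16 genes 1 rose and 0 fell, also when adjusted over the list alone (median 0.05).

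Several immune lists rose in the same animals. Of 18 neutrophil genes 13 rose and 5 did not pass (13 adjusted over the list alone), with a median of 2.06. Of 31 cytokines and chemokines 20 rose and 1 fell (23 and 1 adjusted over the list alone), including interleukin 1 beta (Il1b, 3.55 ± 0.59) and interleukin 1 alpha (Il1a, 3.24 ± 0.65). Of 21 monocyte and macrophage genes 15 rose, with Chil3 at 3.09 ± 0.66, and 13 of 17 complement genes rose, with C4b at 1.88 ± 0.29. Of 20 T cell and cytotoxic genes 9 rose, with granzyme B (Gzmb) at 1.99 ± 0.45 (10 adjusted over the list alone). Camera called the neutrophil and cytokine lists upward (adjusted p = 2.35e-07 for each, and 0.496 with an estimated correlation for each). It did not call the plasma cell, mast cell, MHC class II or interferon lists (adjusted p = 0.686, 0.0867, 0.485 and 0.289, and 0.931, 0.598, 0.893 and 0.893 with an estimated correlation). Of their members, 2 of 12 plasma cell genes rose and 1 fell, 3 of 11 mast cell genes rose, 0 of 7 MHC class II genes passed in limma, and 4 of 23 interferon-stimulated genes rose and 3 fell. Of 18 B cell genes 2 rose, and 0 when adjusted over the list alone. Of 17 epithelial antimicrobial and acute-phase genes 6 rose and 3 fell, with a median of 0.29 (camera adjusted p = 0.168, and 0.626 with an estimated correlation).

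Most lists of epithelial cell types fell. Of 26 genes of mature colonocytes and ion transport 18 fell and 8 did not pass (19 adjusted over the list alone, median -1.29), among them the water channel Aqp8 (-2.57 ± 0.69). Of 16 tight junction genes 12 fell and 1 rose, with claudin 8 (Cldn8) at -2.19 ± 0.55 and occludin (Ocln) at -1.42 ± 0.29. Of 15 crypt base and Wnt target genes 10 fell and 1 rose, including the stem cell receptor Lgr5 (-2.00 ± 0.32) and the transcription factor Ascl2 (-1.48 ± 0.21). Of 17 goblet cell genes 10 fell, such as Best2 (-2.43 ± 0.57) and Clca1 (-2.16 ± 0.40), and 1 rose, the resistin-like Retnlb (3.32 ± 0.89). Of 12 enteroendocrine genes 7 fell, including the hormones Insl5 (-2.94 ± 0.66) and Pyy (-1.84 ± 0.27). Of 24 xenobiotic genes 13 fell and 2 rose, with Cyp2f2 at -3.46 ± 0.45, and 20 of 23 oxidative phosphorylation genes fell by a median of -0.57. A look at single arrays, chosen after the values were seen, showed that the loss was uneven. The mean colonocyte signal was 9.63 and 8.57 in wild-type acute DSS replicates 1 and 3, between 10.92 and 11.02 in the other 3 and between 11.55 and 11.58 in controls. The mean goblet cell signal was 9.99 and 9.16 in those 2 arrays, between 10.78 and 11.16 in the other 3 and between 11.01 and 11.17 in controls. For tight junctions the mean signal was 9.29 and 8.66 in those 2 arrays, between 9.89 and 10.02 in the other 3 and between 10.28 and 10.38 in controls. Without replicate 3 the colonocyte median was -0.79 and 14 genes of that list fell. Of 11 tuft cell genes 1 rose and 2 fell, and that list was not called (camera adjusted p = 0.496, and 0.893 with an estimated correlation). Camera called the colonocyte list downward (adjusted p = 1.45e-05, and 0.527 with an estimated correlation) and the oxidative phosphorylation list too (adjusted p = 2.72e-09, and 0.496 with an estimated correlation). In total 8211 genes passed in wild-type acute DSS, 3863 higher and 4348 lower, of which 580 and 554 differed at least 2-fold. All 8 arrays belonged to 1 series of animal numbers, so that series did not separate the groups. With variances from these 8 arrays alone the calls of Aqp8, Ocln and Clca1 ended (adjusted p = 0.102, 0.0801 and 0.0525).

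Acute DSS in the knockout was compared in the same way. Mptx1 was again the gene with the deepest loss (-4.82 ± 1.02, adjusted p = 0.0156, n = 3 and 6). Lcn2 (2.99 ± 0.72), the chloride channel regulator Clca4b (2.98 ± 0.61), Saa3 (2.77 ± 0.70), the inducible nitric oxide synthase Nos2 (2.77 ± 0.59), Lrg1 (2.56 ± 0.64) and Il1b (2.43 ± 0.57) rose. Further genes that rose were Serpina3n (2.33 ± 0.49), epiregulin (Ereg, 2.25 ± 0.55), the tryptophan-degrading enzyme Ido1 (2.13 ± 0.54) and the interferon-inducible GTPase Iigp1 (2.12 ± 0.51). Slc37a2 (-2.27 ± 0.58), Itih2 (-1.44 ± 0.22) and Wfdc2 (-1.39 ± 0.33) fell, as did the circadian genes Dbp (-1.72 ± 0.41) and Nr1d1 (-1.34 ± 0.33). In the knockout acute controls Dbp and Nr1d1 stood 2.10 and 1.44 above the wild-type acute controls, so their fall need not be an effect of DSS. Of 29 matrix genes 0 passed, with a median of 0.21, and 1 was lower when adjusted over the list alone. Lox stood at 1.20 ± 0.49 and Col8a1 at -0.85 ± 0.24 in limma (adjusted p = 0.215 and 0.0700). Of 18 neutrophil genes 1 rose, Retnlg (1.90 ± 0.47), and 11 when adjusted over the list alone, with a median of 1.13. Of 31 cytokines and chemokines 1 rose, Il1b, and 14 when adjusted over the list alone. Camera called the matrix, neutrophil and cytokine lists upward in knockout too (adjusted p = 0.0399, 4.46e-08 and 7.49e-09). With an estimated correlation it did not (adjusted p = 0.71, 0.308 and 0.308). At the preset correlation camera called 15 lists upward and 9 downward in knockout, against 11 and 7 in wild-type acute DSS. Of 26 colonocyte genes 3 fell, including the phosphate transporter Slc20a1 (-1.21 ± 0.31). Of 16 smooth muscle genes 0 passed and 12 were lower when adjusted over the list alone (median -0.45, camera adjusted p = 4.46e-08, and 0.308 with an estimated correlation).

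In all 223 genes passed in knockout acute DSS, 53 higher and 170 lower, and 3251 had an unadjusted p under 0.05. The 6 knockout mice on DSS came from 2 series of animal numbers and the controls from 1 of them. Within that series (3 against 3), or with series in the model, 3 genes passed, all lower, and they were named after their values were seen. They were the detoxifying enzymes Ephx1 (-1.01 ± 0.16), Gstm2 (-0.70 ± 0.12) and Gstt1 (-0.59 ± 0.11). Both fits rest on the same difference for each gene, so they are not separate checks. The calls of the other genes named for this comparison ended in both fits, with series in the model at -4.15 for Mptx1, 2.98 for Saa3, 2.73 for Lcn2, 1.60 for Clca4b and 1.44 for Nos2 (adjusted p = 0.135, 0.132, 0.159, 0.186 and 0.213). What ended these calls was not tested. Within the controls' series the smooth muscle median was -0.22 and the colonocyte median -0.24, against -0.45 for each over all arrays, and the neutrophil median was 0.76 against 1.13. The mean smooth muscle signal was 10.40 to 10.65 in the 3 DSS arrays with plain numbers, 10.77 to 11.15 in the 3 of the controls' series and 11.08 to 11.37 in the controls. Without single arrays the count ran from 15, without knockout acute control replicate 1, to 630, without knockout acute DSS replicate 5.

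Knockout and wild-type mice were then compared directly under acute DSS, which also holds differences that were present without DSS. Ido1, Apol10a, Xpnpep2 and the interferon list (median 0.69) were higher in knockout acute controls as well. Camera also called the MHC class I and T cell lists upward there (medians 0.33 and 0.31), though neither with an estimated correlation. Stromal and neutrophil transcripts were lower in knockout, and epithelial, interferon and MHC class I transcripts were higher. Timp1 led the lower genes, followed by haptoglobin (Hp, -2.63 ± 0.46), the secreted peptidase inhibitor Pi15 (-2.46 ± 0.31), Saa3 (-2.42 ± 0.60), the neutrophil collagenase Mmp8 (-2.35 ± 0.51), Lcn2 (-2.28 ± 0.62) and Lox (-2.21 ± 0.42), with n = 6 and 5. The immunoglobulin transcripts Igkv9-120 (-2.72 ± 0.61) and Igha (-2.19 ± 0.55) and Ifitm6 of the interferon-induced transmembrane family (-2.28 ± 0.42) were lower too. Ido1 was higher by 3.91 ± 0.47 (adjusted p = 8.21e-07), the aminopeptidase Xpnpep2 by 2.77 ± 0.24 (adjusted p = 6.46e-09) and the interferon-induced chemokine Cxcl9 by 2.52 ± 0.55. Sectm1b (2.53 ± 0.53), Apol10a (2.52 ± 0.61), Reg4 (2.36 ± 0.49), Gsdmc4 (2.35 ± 0.27), Selenbp1 (2.31 ± 0.36) and Akr1c14 (2.30 ± 0.41) were also higher. Of the other inhibitors of the family, Timp2 was lower by -1.36 ± 0.15 (adjusted p = 2.11e-07) and Timp3 by -0.99 ± 0.23, while Timp4 stood at -0.06 ± 0.24 (adjusted p = 0.882). Syn1, whose gene neighbours Timp1 in the mouse assembly GRCm38.p6, was lower by -0.88 ± 0.08 (adjusted p = 6.46e-09).

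Of 29 matrix genes 28 were lower in knockout acute DSS than in wild-type acute DSS and 1 did not pass (28 adjusted over the list alone), with a median of -1.14. Col12a1 (-1.95 ± 0.24) and Col18a1 (-1.67 ± 0.24) followed Lox. The mean matrix signal was 9.98 ± 0.48 (SD, n = 6) in knockout and 11.13 ± 0.42 (SD, n = 5) in wild type. All 6 knockout arrays lay below all 5 wild-type arrays, and an exact two-sided permutation test gave p = 0.00433. The gap was narrow, with knockout replicate 6 at 10.65 and wild-type replicate 4 at 10.68. Wild-type replicates 1 and 3 stood highest, at 11.58 and 11.54, and the others lay between 10.68 and 11.08. Of 19 myofibroblast genes 17 were lower, including Inhba (-2.13 ± 0.28), Grem1 (-1.54 ± 0.38) and the pericyte receptor Pdgfrb (-1.47 ± 0.19). Of 25 proteases 20 were lower, with Mmp10 at -2.18 ± 0.52 and Mmp13 at -2.09 ± 0.59, and all 14 endothelial genes were lower, with Cdh5 at -1.21 ± 0.25. Of 18 neutrophil genes 12 were lower and 1 higher, with Retnlg at -1.99 ± 0.40 and S100a8 at -1.88 ± 0.51. The mean neutrophil signal was 7.74 ± 0.58 (SD, n = 6) in knockout and 8.72 ± 0.81 (SD, n = 5) in wild type, with 4 of 6 knockout arrays below all wild-type arrays (permutation p = 0.0390). Within the plain-number series 2 of 3 lay below and the neutrophil difference did not pass (permutation p = 0.179). Wild-type replicates 1 and 3 had mean neutrophil signals of 9.06 and 9.94, and the other wild-type arrays lay between 7.995 and 8.605. Of 31 cytokines and chemokines 12 were lower, among them Cxcl2 (-2.16 ± 0.48) and the prostaglandin synthase Ptgs2 (-1.88 ± 0.41), and 2 were higher, among them Cxcl9. Of 16 smooth muscle genes 7 were lower (8 adjusted over the list alone, median -0.43, camera adjusted p = 2.39e-04, and 0.473 with an estimated correlation). Camera called the matrix list (adjusted p = 3.39e-22, and 0.234 with an estimated correlation), the endothelial list (1.06e-08, and 0.302 with an estimated correlation) and the neutrophil list (1.72e-04, and 0.412 with an estimated correlation) downward.

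Epithelial and interferon genes ran the other way. Of 26 colonocyte genes 14 were higher in knockout (19 adjusted over the list alone, median 1.01), including the mineralocorticoid receptor Nr3c2 (1.28 ± 0.26) and the amino acid transporter Slc6a14 (1.38 ± 0.40). The mean colonocyte signal lay above all 5 wild-type arrays in 4 of 6 knockout arrays (permutation p = 0.0325), and in 2 of 3 within the plain-number series (permutation p = 0.196). Wild-type acute DSS replicates 1 and 3, at 9.63 and 8.57, carried much of this difference, since the other 3 lay between 10.92 and 11.02 and the knockout arrays between 10.80 and 11.46. Without replicate 1 the colonocyte median was 0.85 and without replicate 3 it was 0.55, with 5 genes higher each time. Of 17 goblet cell genes 10 were higher, among them Best2 (1.77 ± 0.47), the secretory lineage factor Atoh1 (1.70 ± 0.39) and Clca1 (1.40 ± 0.33). The mean goblet cell signal was 9.99 and 9.16 in wild-type replicates 1 and 3, 10.78 to 11.16 in the other 3 and 10.71 to 11.58 in knockout. Of 16 tight junction genes 13 were higher, such as Cldn8 (1.28 ± 0.45), and 2 lower, including claudin 1 (Cldn1, -1.74 ± 0.30). The mean tight junction signal was 9.29 and 8.66 in wild-type replicates 1 and 3, 9.89 to 10.02 in the other 3 and 9.74 to 10.20 in knockout. Of 23 oxidative phosphorylation genes 20 were higher, by a median of 0.40. Of 23 interferon-stimulated genes 16 were higher and 7 did not pass (19 higher adjusted over the list alone, median 1.00), including Iigp1 (2.08 ± 0.43), the antiviral Ifit2 (1.85 ± 0.25) and the GTPase Irgm1 (1.72 ± 0.23). Of 10 MHC class I genes 8 were higher, among them the peptide transporter Tap1 (1.51 ± 0.24) and the immunoproteasome subunits Psmb8 (1.46 ± 0.21) and Psmb9 (1.33 ± 0.16). Of 7 MHC class II genes 2 were higher, and camera did not call that list (adjusted p = 0.0683, and 0.619 with an estimated correlation). Of 20 T cell and cytotoxic genes 7 were higher, with granzyme A (Gzma) at 1.49 ± 0.23 and Nkg7 at 1.37 ± 0.25, and 2 were lower. Camera called the colonocyte list (adjusted p = 1.40e-05, and 0.412 with an estimated correlation), the interferon list (1.58e-10, and 0.289 with an estimated correlation) and the MHC class I list (1.38e-07, and 0.234 with an estimated correlation) upward.

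The comparison under acute DSS passed 6170 genes, 3142 higher and 3028 lower in knockout, 264 and 370 of them at least 2-fold. Within the series of plain animal numbers (3 knockout and 5 wild-type arrays) 6538 genes passed, 4807 of them shared. The matrix median was -1.15 there and the interferon median 1.10. With variances from these 11 arrays alone, 2239 genes passed, and the calls of Saa3, Lcn2, Mmp8, Cxcl9, Sectm1b, Akr1c14, Timp3, Grem1, Mmp10, Mmp13, S100a8, Cxcl2, Ptgs2, Cdh5, Slc6a14, Nr3c2, Best2, Atoh1, Clca1 and Cldn8 ended. Grem1 and S100a8 also lost theirs with animal series in the model, at -1.10 and -1.49 (adjusted p = 0.0627 and 0.0680). Cldn8 lost its call without any one of 6 arrays (adjusted p = 0.0690 without knockout acute DSS replicate 1), and Slc6a14 without wild-type acute DSS replicate 1 or 3 (0.0581 and 0.0615).

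**Figure D2:**
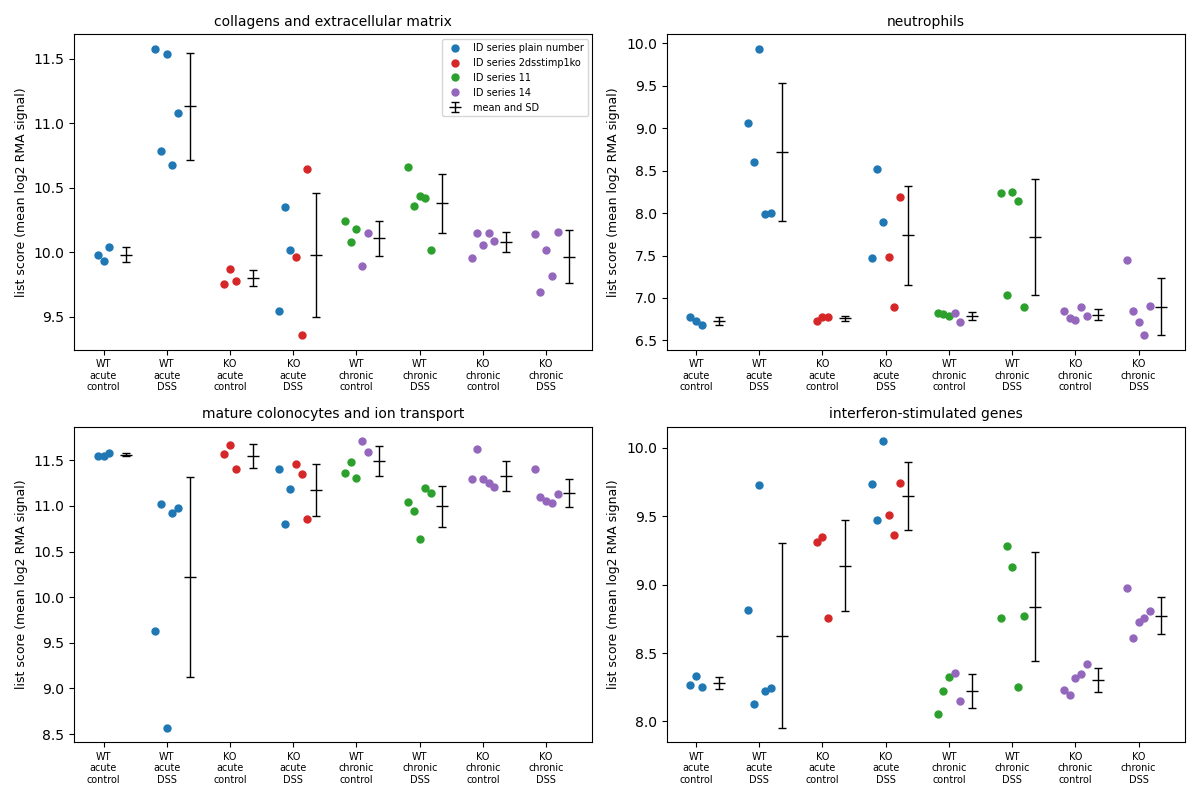
Mean log2 signal of 4 gene lists in each array by group, with the group mean and SD and the series of animal numbers in colour. The matrix score averaged 11.13 in wild-type acute DSS and 9.98 in knockout acute DSS, and the interferon score 8.63 and 9.65.

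Whether the acute response itself differed between genotypes was tested as an interaction. Interactions were negative for matrix genes and for the acute-phase genes Saa3 and Hp, and positive for several colonocyte and tight junction genes. The interaction was -3.51 ± 1.0 for Saa3 (adjusted p = 0.0219), -2.79 ± 0.77 for Hp and -2.31 ± 0.68 for Retnlg. The protease Pappa (-2.21 ± 0.52), the peptidase inhibitor Pi15 (-2.23 ± 0.52), the signalling regulator Rgs2 (-2.36 ± 0.48) and the carboxylesterase Ces1g (-3.86 ± 0.94) had negative interactions as well. Gsdmc4 (2.55 ± 0.45), the calpain Capn13 (2.86 ± 0.68), Selenbp1 (2.40 ± 0.61), the magnesium channel Trpm6 (2.33 ± 0.49) and the deiodinase Dio1 (2.24 ± 0.55) had positive ones. Of 29 matrix genes 16 had a negative interaction (21 adjusted over the list alone, median -0.88), and 9 of 23 oxidative phosphorylation genes a positive one. Of 26 colonocyte genes 3 had a positive interaction (6 adjusted over the list alone) and of 16 tight junction genes 4 (11 adjusted over the list alone). Wild-type acute DSS replicates 1 and 3 weighed heavily on both lists. Their colonocyte scores were 9.63 and 8.57 against 10.92 to 11.02 in the other 3, and their tight junction scores 9.29 and 8.66 against 9.89 to 10.02. Of 17 epithelial antimicrobial and acute-phase genes 1 had a negative interaction, with a list median of 0.31 (camera adjusted p = 0.686, and 0.880 with an estimated correlation). The interferon list was not called, with 2 of 23 genes positive and a median of 0.19 (camera adjusted p = 0.326, and 0.880 with an estimated correlation). Camera called the matrix list (adjusted p = 1.24e-12, and 0.604 with an estimated correlation). In all 2444 genes passed, 1297 positive and 1147 negative, with n = 3, 5, 3 and 6. Of these, 2307 had passed in wild-type acute DSS and 2295 of them had the smaller change in knockout, a share that the contrast favours because it contains the wild-type effect. With animal series in the model 1308 genes passed, and in fits of these 4 groups alone 536, where the calls of Saa3, Hp, Retnlg, Pi15, Pappa, Ces1g, Selenbp1 and Dio1 ended. Of the 55 genes that passed here and met the naming rule, 24 lost their call with series in the model and 25 without 1 array or another. Without wild-type acute control replicate 3 the count was 1257 and the call of Saa3 ended (adjusted p = 0.0521). Without knockout acute DSS replicate 6 it was 3981.

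Across genes, the acute DSS effects of the genotypes correlated with Pearson's r = 0.602 and Spearman's rho = 0.461, and the chronic effects with r = 0.675 and rho = 0.425. Genes are not independent replicates, so no p is given. In the acute phase 157 genes passed in both genotypes with the same sign, against 47.3 expected from the 2 counts, and in the chronic phase 561 against 122.

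Chronic DSS in wild-type mice raised epithelial antimicrobial, T cell, plasma cell, mast cell and neutrophil transcripts. Reg3g (5.38 ± 0.95), Plet1, a surface protein of epithelial progenitors (4.91 ± 0.52), Sptssb, a subunit of the sphingolipid-forming enzyme (4.79 ± 0.67), Retnlb (4.48 ± 0.77) and Reg3b (4.39 ± 1.08) rose most (n = 5 and 5). An immunoglobulin kappa segment, Igkv4-91 (3.59 ± 0.72), the retinol dehydrogenase Dhrs9 (3.52 ± 0.45), Clca4b (3.38 ± 0.55), Saa3 (3.36 ± 0.63) and the mast cell protease Mcpt2 (3.03 ± 0.47) followed. Mptx1 (-5.05 ± 0.92), Slc37a2 (-3.93 ± 0.52), Casp14 (-3.05 ± 0.43), Cyp2f2 (-2.85 ± 0.39), Hoxd13 (-2.64 ± 0.49), Cyp2c68 (-2.55 ± 0.62) and the fucosyltransferase Fut9 (-2.43 ± 0.35) fell. Tgm3 (-3.28 ± 0.91), Atp12a (-2.86 ± 0.80) and Hoxb13 (-2.70 ± 0.78) fell too, but within the series that held both groups their adjusted p values were 0.0501, 0.0577 and 0.0569. Without wild-type chronic DSS replicate 2, Tgm3 and Hoxb13 stood at 0.0550 and 0.0647. Of 17 epithelial antimicrobial and acute-phase genes 8 rose (11 adjusted over the list alone, median 1.47, camera adjusted p = 1.94e-07, and 0.0508 with an estimated correlation). Of 20 T cell genes 16 rose (20 adjusted over the list alone, median 0.63), including Cd3g (1.22 ± 0.25), the costimulator Icos (0.99 ± 0.23) and Gzmb (1.44 ± 0.39). Of 12 plasma cell genes 9 rose (12 adjusted over the list alone), with the immunoglobulin joining chain Jchain at 1.93 ± 0.39, Derl3 at 1.55 ± 0.26 and Mzb1 at 1.52 ± 0.30. Of 11 mast cell genes 7 rose, including Mcpt1 (2.59 ± 0.41) and Cpa3 (1.65 ± 0.24). Of 16 unfolded protein response genes 11 rose (14 adjusted over the list alone), such as asparagine synthetase (Asns, 1.11 ± 0.21). Of 18 B cell genes 0 passed in limma, and also 0 when adjusted over the list alone. Of 18 neutrophil genes 9 rose (13 adjusted over the list alone), and of 29 matrix genes 5 rose and 1 fell, with Lox at 1.35 ± 0.44. Within that series Lox and Gzmb did not pass (adjusted p = 0.103 and 0.0634), and Lox lost its call without any one of 7 arrays (0.111 without wild-type chronic DSS replicate 3). Camera called the T cell list (adjusted p = 2.21e-12, and 0.176 with an estimated correlation), the plasma cell list (6.42e-11, and 0.110 with an estimated correlation) and the mast cell list (1.36e-08, and 0.0508 with an estimated correlation) upward. In all 2864 genes passed, 1154 higher and 1710 lower, and 2250 within the series that held all 5 DSS and 3 control arrays, 1999 of them shared.

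Chronic DSS in the knockout raised epithelial genes such as Reg3g and Retnlb, and 2 mast cell proteases. Reg3g (4.07 ± 0.95), Retnlb (4.06 ± 0.77), Sptssb (2.74 ± 0.67), Clca4b (2.33 ± 0.55), Mcpt2 (2.27 ± 0.47), Mcpt1 (2.25 ± 0.41) and Plet1 (2.12 ± 0.52) rose (n = 5 and 5). Mptx1 (-3.73 ± 0.92), Slc37a2 (-2.22 ± 0.52), Itih2 (-1.76 ± 0.20), Capsl (-1.67 ± 0.15), Cyp2f2 (-1.65 ± 0.39), Wfdc2 (-1.64 ± 0.29) and Fut9 (-1.62 ± 0.35) fell. Reg3b (3.74 ± 1.08), the lipid transporter Abca12 (2.77 ± 0.87), Slc3a1 (2.14 ± 0.66), Tgm3 (-2.92 ± 0.91) and Hoxb13 (-2.68 ± 0.78) passed with all arrays, and each lost its call without knockout chronic DSS replicate 4 (adjusted p = 0.112, 0.139, 0.0854, 0.164 and 0.114). Of 11 mast cell genes 2 rose (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0156, and 0.932 with an estimated correlation). Of 20 T cell genes 4 rose (5 adjusted over the list alone), with Cd3g at 1.27 ± 0.25. Of 23 interferon-stimulated genes 2 rose (5 adjusted over the list alone), Ifit1 (1.73 ± 0.37) and Oas3 (0.92 ± 0.27), of which Oas3 lost its call without any one of 6 arrays (adjusted p = 0.0574 without knockout chronic DSS replicate 3). Of 18 neutrophil genes 0 passed in limma's test and also 0 when adjusted over the list alone, with a median of 0.12. Of 29 matrix genes 1 fell, Col8a1 (-0.97 ± 0.22). Camera called the T cell list (adjusted p = 1.04e-07, and 0.932 with an estimated correlation). In all 1583 genes passed, 492 higher and 1091 lower, all 10 arrays being of 1 series. The count was 893 without knockout chronic DSS replicate 3, 930 without replicate 4, 1029 without knockout chronic control replicate 1 and 995 without control replicate 3.

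Genotype was also compared in the controls. In acute controls, 6 of 23 interferon-stimulated genes and the circadian gene Dbp were higher in knockout (n = 3 and 3). The antiviral helicase Ddx60 (2.30 ± 0.37, adjusted p = 0.00274), the oligoadenylate synthetases Oas3 (2.01 ± 0.34) and Oasl2 (1.85 ± 0.38), Ifit1 (1.85 ± 0.48), Ido1 (2.43 ± 0.63) and Apol10a (3.25 ± 0.83) were higher. So were Plet1 (2.90 ± 0.68), the calcium binder S100g (2.42 ± 0.57), Xpnpep2 (2.23 ± 0.32), the clock output gene Dbp (2.10 ± 0.47) and carbonic anhydrase 12 (Car12, 1.97 ± 0.47). The co-receptor Klb (-1.32 ± 0.32), the creatine transporter Slc16a12 (-1.25 ± 0.27), Capsl (-1.14 ± 0.19) and Bex4 (-0.96 ± 0.13) were lower. Of 23 interferon-stimulated genes 6 were higher (12 adjusted over the list alone, median 0.69), and camera called the list (adjusted p = 3.93e-13, and 0.977 with an estimated correlation). The interferon score was 9.14 ± 0.33 (SD, n = 3) in knockout and 8.28 ± 0.04 (SD, n = 3) in wild type, with all 3 knockout arrays higher and p = 0.10 in the exact two-sided permutation test, the smallest that 3 against 3 can give. Of 20 T cell genes 0 passed in limma's test and 8 were higher when adjusted over the list alone. Of 10 MHC class I genes 0 passed and 5 were higher when adjusted over the list alone (median 0.33). Camera called the T cell and MHC class I lists upward (adjusted p = 3.02e-06 and 2.24e-05, and 0.977 with an estimated correlation for each). In all 223 genes passed, 68 higher and 155 lower. Every knockout array belonged to 1 animal series and every wild-type array to another, so series and genotype cannot be told apart in these arrays. With series in the model, estimated from other groups, 361 genes passed, of which 35 were shared. Ido1 (4.79), Capsl and Bex4 were among them. Plet1 did not pass at 3.47 ± 0.96 (adjusted p = 0.0559), a larger difference with a larger SE. The calls of the other genes named also ended, at 2.62 for Apol10a, 1.81 for Oasl2, 1.80 for Dbp, 1.64 for Oas3, 1.5 for Ifit1, 1.49 for Xpnpep2, 1.31 for Ddx60, 0.91 for Car12, 0.16 for S100g, -0.69 for Klb and -1.16 for Slc16a12. The ended calls do not show that series was the source of these differences. Without single arrays the count lay between 23, without wild-type acute control replicate 3, and 133, without knockout acute control replicate 3. Of the 15 genes named, only Ddx60, Oas3, Xpnpep2, Capsl and Bex4 kept their calls without each array in turn. The calls of Apol10a, Ido1 and Dbp ended without any one of the 6 arrays, those of S100g, Ifit1 and Klb without any one of 5, those of Plet1 and Car12 of 4, that of Oasl2 of 3 and that of Slc16a12 of 2.

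In chronic controls 20 genes passed, 14 higher and 6 lower in knockout (n = 5 and 5), with 1886 at an unadjusted p under 0.05. Xpnpep2 (1.60 ± 0.25), the endosomal adaptor Wdfy1 (0.92 ± 0.09, adjusted p = 2.30e-07) and the phospholipase Plcd3 (0.73 ± 0.10) were higher. Plet1 (2.77 ± 0.52), the collagen Col8a1 (1.13 ± 0.22), Ddah1 (1.26 ± 0.26), Casp14 (-2.10 ± 0.43) and Hoxd12 (-1.24 ± 0.24) passed as well. With animal series in the model none of these 5 passed, at 2.28 ± 0.69, 1.10, 0.33, -1.87 and -0.18 (adjusted p = 0.585, 0.574, 0.870, 0.585 and 0.917). Within the series that held all 5 knockout and 2 wild-type arrays, 4 genes passed, of which Wdfy1 (0.84 ± 0.12) and Plcd3 (0.72 ± 0.13) were shared. Xpnpep2 (1.69 ± 0.34, adjusted p = 0.126) and Plet1 (2.28 ± 0.72, adjusted p = 0.866) did not pass there. The other 2, chosen after their values were seen, were the mitochondrial Chchd10 (2.37 ± 0.40) and the B lineage gene Vpreb3 (-1.94 ± 0.34). The fit within 1 series and the fit with series in the model rest on the same differences, so they are not separate checks. The count ran from 4, without wild-type chronic control replicate 2, to 280, without knockout chronic control replicate 2.

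Under chronic DSS, haptoglobin (Hp, -2.04 ± 0.48), Retnlg (-1.52 ± 0.42), the gelatinase Mmp9 (-1.28 ± 0.33), the mast cell carboxypeptidase Cpa3 (-1.0 ± 0.24), the retinal dehydrogenase Aldh1a3 (-1.18 ± 0.31) and the immunoglobulin segment Igkv6-20 (-2.04 ± 0.52) were lower in knockout (n = 5 and 5). Xpnpep2 (2.07 ± 0.25), AI506816 (1.17 ± 0.21), Rbm12b2 (0.90 ± 0.15), Zfp942 (0.87 ± 0.16), Wdfy1 (0.76 ± 0.09) and Clk1 (0.68 ± 0.11) were higher. Of 29 matrix genes 0 passed in limma's test and 11 were lower when adjusted over the list alone (median -0.38, camera adjusted p = 7.91e-07, and 0.742 with an estimated correlation). Of 18 neutrophil genes 1 was lower, Retnlg (6 adjusted over the list alone, median -0.80), and of 11 mast cell genes 2 were lower. In all 495 genes passed, 235 higher and 260 lower, and 3378 had an unadjusted p under 0.05. The balance of directions depended on the processing, with 237 higher and 412 lower after cyclic loess and 1123 and 545 when all transcript clusters were tested. The genotypes came from different animal series, and with series in the model 19 genes passed, of which 5 were shared and Xpnpep2 (2.23 ± 0.41) was one. None of the other genes named for this comparison passed then. AI506816, Rbm12b2, Zfp942, Wdfy1 and Clk1 stood at 0.58, 0.84, 0.59, 0.62 and 0.63 (adjusted p = 0.601, 0.276, 0.563, 0.0946 and 0.226). Hp, Retnlg, Mmp9, Cpa3, Aldh1a3 and Igkv6-20 stood at -1.87, -1.18, -1.03, -0.88, -0.67 and -2.71 (adjusted p = 0.599, 0.765, 0.723, 0.637, 0.844 and 0.361). Without wild-type chronic DSS replicate 3 the count was 58, and without knockout chronic DSS replicate 1 it was 1010. The calls of Hp, Mmp9, Aldh1a3, Igkv6-20 and Retnlg ended without wild-type chronic DSS replicate 3 (adjusted p = 0.0891, 0.139, 0.185, 0.160 and 0.163), and that of Cpa3 without wild-type chronic DSS replicate 1 (0.0829).

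The chronic interaction passed 84 genes, 54 positive and 30 negative (n = 5 in each of 4 groups). Ltbp2, a latent TGF-beta binding protein (-0.77 ± 0.18), the protease Mmp28 (-0.79 ± 0.19), the secretory chaperone Fkbp11 (-0.77 ± 0.13) and Igkv6-20 (-3.19 ± 0.74) had negative interactions, and Zfp942 (1.05 ± 0.23), Guf1 (0.90 ± 0.17), Zfp944 (0.79 ± 0.15) and Clk1 (0.77 ± 0.15) positive ones. Of 12 plasma cell genes 1 had a negative interaction, Fkbp11 (7 adjusted over the list alone, median -0.78, camera adjusted p = 2.25e-06, and 0.789 with an estimated correlation). The count ran from 5, without knockout chronic DSS replicate 3, to 422, without knockout chronic control replicate 2. Of the 8 genes named here only Fkbp11 kept its call without each array in turn.

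The chronic and acute responses were compared within each genotype. In wild type 3392 genes differed, 1854 higher and 1538 lower in the chronic response. The immunoglobulin heavy chain Ighm (4.14 ± 1.07), Ctse (3.0 ± 0.81), Reg4 (2.91 ± 0.79), Gsdmc4 (2.81 ± 0.43) and Ceacam10 (2.56 ± 0.45) stood higher, and Pi15 (-3.15 ± 0.50), Cxcl2 (-3.11 ± 0.77), Hp (-2.57 ± 0.73), the fatty acid transporter Cd36 (-2.37 ± 0.58) and the deiodinase Dio2 (-2.35 ± 0.44) lower. Of 29 matrix genes 16 were lower (23 adjusted over the list alone), 18 of 23 oxidative phosphorylation genes were higher and 6 of 12 plasma cell genes were higher. Camera called these 3 lists (adjusted p = 2.81e-10, 6.49e-11 and 3.35e-04, and 0.558 with an estimated correlation for each). In knockout 2 genes differed, Ephx1 (1.14 ± 0.19) and Foxred2 (-0.65 ± 0.12), with 2279 at an unadjusted p under 0.05, and neither passed in a fit of those 4 groups alone. The wild-type count was 1937 without wild-type acute control replicate 3, and the knockout count was 0 without knockout chronic DSS replicate 2 and 11 without replicate 1. Of the 76 genes that passed in wild type and met the naming rule, 26 lost their call without 1 array or another. The phases used separate animals and separate controls, from different animal series.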

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

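Of the tests weighed here, the one on the epithelial share of the tissue was chosen after the results were seen. So were the permutation tests of list scores within and between animal series. The bars for the matrix and interferon lists within or between series were set before the result.

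Single arrays stood apart from the rest of their group in 7 of 78 tests, where chance gives about 1 in 20 groups, or 3.9. Timp1 was 8.68 in knockout acute DSS replicate 6 and between 7.10 and 7.68 in the other 5. In knockout acute DSS replicate 4 the Y-linked Eif2s3y was 9.55 (4.71 to 4.88 in the others) and Xist 5.81 (12.19 to 12.54), and its adipocyte score was 8.75 (7.52 to 7.96). Xist was 11.76 in knockout chronic DSS replicate 2 (12.37 to 12.57 in the others). The mature colonocyte score was 11.62 in knockout chronic control replicate 2 (11.21 to 11.29) and 11.41 in knockout chronic DSS replicate 1 (11.03 to 11.13).

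Effects differed between groups by tests of the difference itself. The genotype by DSS interaction passed 2444 genes in the acute phase and 84 in the chronic phase. The chronic DSS effect differed from the acute one for 3392 genes in wild type and 2 in knockout. Among the 12101 transcript clusters without a listed gene, which the comparisons did not use, 970 were higher and 663 lower in wild-type acute DSS than in controls.

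Other divisions of the same arrays into groups of the same sizes were fitted for each count, and the real division is included in each number of divisions. By that bar chance was excluded for acute DSS in wild type (1 of 56 divisions gave as many, 8211 genes against at most 6127 in another), chronic DSS in wild type (1 of 100, 2864 against 158) and chronic DSS in knockout (1 of 100, 1583 against 612). By that bar it was excluded as well for knockout against wild type in acute DSS (1 of 100, 6170 against 4036). Those divisions also mixed animal series, of which 1 held no wild-type mice, but within the plain-number series 6538 genes passed. Knockout against wild type in chronic controls (3 of 100, 20 against 143) and in chronic DSS (2 of 100, 495 against 506) met the bar too. Other divisions gave more genes in both, though, so the counts do not firmly exclude chance there. These divisions mix the animal series, over which genotype was unbalanced, and with series in the model 5 genes passed in chronic controls and 19 in chronic DSS, so series is not excluded there. The division that gave 143 set 5 arrays of 1 series against a group with all 3 of the other series, and within 1 series 4 genes passed. The acute interaction (1 of 100, 2444 against 1599), the chronic interaction (1 of 100, 84 against 34) and the chronic against acute effect in wild type (1 of 100, 3392 against 20) met the bar too. Their divisions shuffled genotype or phase within each treatment, which removes any genotype or phase difference along with the interaction. They therefore do not test the interaction alone. Chance cannot be excluded for acute DSS in knockout, where 6 of 84 divisions gave as many as the real 223. The highest, 3462, divided the arrays by animal series, so these arrays are structured by series, and within 1 series 3 genes passed. It cannot be excluded for the chronic against acute effect in knockout either (9 of 100, 2 against 833). The division that gave 833 left the controls in place and put all 3 plain-number DSS arrays among those called chronic. For the acute controls, 10 divisions are too few to reach a share under 0.05 (1 of 10, 223 against 1).

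Collagen and matrix genes were lower in knockout than in wild type under acute DSS, by a median of -1.14 over 29 genes. Animal series was excluded as the cause, since within the plain-number series the median was -1.15 and 3 of 3 knockout arrays lay below all 5 wild-type arrays. Without the 2 arrays with Y-linked signal the median was -1.12. A larger epithelial share as the whole cause would lower matrix, T cell and smooth muscle genes alike if nothing else differed. The matrix score minus the T cell score was 2.13 ± 0.36 (SD, n = 6) in knockout and 3.53 ± 0.22 (SD, n = 5) in wild type (difference -1.40, exact permutation p = 0.00216, the smallest these arrays can give). The T cell score was already higher in knockout acute controls (7.39 ± 0.15, SD, n = 3) than in wild-type ones (6.98 ± 0.11, SD, n = 3). The 2 lists did not move alike, but the difference holds that offset, so the test does not exclude a larger epithelial share. Smooth muscle lay on the side of matrix (score difference -0.43, exact permutation p = 0.0519, and -0.69 with p = 0.0179, the smallest possible, within the plain-number series, which lay 0.52 below the second series among knockout arrays). In that second series the smooth muscle score was 11.02 and the matrix score 9.99, against 11.19 and 11.13 in wild type. These values argue against less muscle wall as the whole cause in those 3 arrays, although their series held no wild-type mice. Less of the muscle wall in the tissue sampled stays open as a part of the cause, as do a weaker stromal response without Timp1 and a milder DSS injury, neither of which was tested.

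Interferon-stimulated genes were higher in knockout in acute controls (median 0.69) and under acute DSS (median 1.00). No single control array made the first difference, since the lowest median with 1 array left out was 0.58. Animal series and genotype cannot be told apart in the acute controls, where each genotype held 1 series, and among knockout acute DSS arrays the score of the second series minus that of the plain numbers was -0.21 (exact permutation p = 0.5). Under acute DSS the median within the plain-number series was 1.10, but wild-type acute DSS replicate 3 reached 9.73, and 2 of 3 knockout arrays exceeded all wild-type arrays (exact permutation p = 0.0536). Series cannot produce a difference within itself, and the score difference was 1.12 there against 1.02 over all arrays. The bar set before the result, all 3 knockout arrays above all 5 wild-type arrays, was not met, so the test did not exclude series as the cause over all arrays.

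Clock genes differed between knockout and wild type in acute controls. Of 10 genes of the Dbp group 4 were higher, Dbp (2.10 ± 0.47), Nr1d1 (1.44 ± 0.38), Nr1d2 (1.24 ± 0.31) and Bhlhe41 (1.03 ± 0.22), with a median of 0.99, and the 4 measured genes of the opposite phase had a median of -0.78, of which 0 passed in limma's test, with Arntl at -1.26 ± 0.36 (adjusted p = 0.0767). The clock score, the Dbp group minus the opposite phase, was higher in knockout by 1.74 in acute controls (exact permutation p = 0.10, the smallest that 3 against 3 can give). The difference was -0.06 in acute DSS, -0.56 in chronic controls and 0.10 in chronic DSS (exact permutation p = 0.775, 0.333 and 0.778). These values argue against a constant effect of the Timp1 genotype, but no test compared the settings, so it was not excluded. The opposite shifts are consistent with different times of day at collection, which the labels do not give.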

How the results depend on the processing

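Leaving out the 2 arrays with Y-linked signal was chosen after the data were seen, and the other alternatives before the data were examined. No paired analysis was possible because the animal numbers in the titles do not recur between groups. With the correlation estimated per list, 0 gene lists were called by camera in each of the 12 comparisons. The 10 of 10 simulated lists called so held genes that varied independently, whereas the estimated correlation of the matrix list was 0.67. The simulation therefore does not show whether lists of correlated genes could be called. The count for acute DSS in wild type stayed within 1.5 times 8211 under every alternative run, and so did that for the chronic against acute effect in wild type under every alternative other than leaving out arrays. No named gene that passed changed direction under any alternative, and no alternative moved the median of all genes by more than 0.1. Where a count moved, the cause was not tested. Array weights raised the counts to 3247 for acute DSS in knockout, 4953 and 3692 for chronic DSS in wild type and knockout, 3041, 1348 and 1624 for genotype in acute controls, chronic controls and chronic DSS, 5000 and 1832 for the acute and chronic interactions and 1249 for the chronic against acute effect in knockout. With animal series as a covariate they were 3 for acute DSS in knockout, 361, 5 and 19 for genotype in acute controls, chronic controls and chronic DSS, 1308 and 186 for the interactions and 23 for the chronic against acute effect in knockout. Within 1 series they were 3 for acute DSS in knockout and 4 for genotype in chronic controls. For these comparisons the fits within 1 series rest on the same differences as the covariate fits. In fits of the groups compared alone they were 0 for acute DSS in knockout (limma, 3251 at an unadjusted p under 0.05 with all arrays), 964, 2239, 6 and 12 for genotype in acute controls, acute DSS, chronic controls and chronic DSS, 536 for the acute interaction and 0 for the chronic against acute effect in knockout. Testing all clusters gave 3525 for chronic DSS in knockout, 32 and 1668 for genotype in chronic controls and chronic DSS and 595 for the chronic interaction. Cyclic loess gave 36 for genotype in chronic controls, 153 for the chronic interaction (66 positive and 87 negative, against 54 and 30), 4 for the chronic against acute effect in knockout and 7 in place of 12 lists for chronic DSS in knockout. Without the dimmest genes the chronic interaction gave 146. With sex as a covariate acute DSS in knockout gave 115 and genotype in acute controls 105, and without the 2 arrays with Y-linked signal 80 and 129, and 0 for the chronic against acute effect in knockout. Leaving out 1 array at a time gave 5824 to 8428 and 15 to 630 for acute DSS in wild type and knockout, 2030 to 2652 and 893 to 1786 for chronic DSS, and 23 to 133, 4604 to 6989, 4 to 280 and 58 to 1010 for genotype in acute controls, acute DSS, chronic controls and chronic DSS. It gave 1257 to 3981 and 5 to 422 for the interactions, and 1937 to 4305 and 0 to 11 for the chronic against acute effects. Timp1 under chronic DSS lay between -1.68 and -1.16 and lost its call without any one of 6 arrays, and in chronic controls, where it was not called, it ranged from -0.066 to 0.090 and changed sign without any one of 4 arrays. The correlation of DSS effects between genotypes ranged from 0.448 to 0.655 in the acute and 0.583 to 0.706 in the chronic phase with 1 array left out, with jackknife standard errors of 0.173 and 0.124.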

Other observations

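The genes and values in this part were chosen after the data were seen.

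Hoxb13 varied widely in 3 of the 4 DSS groups, with SDs of 1.75 in knockout acute DSS (n = 6) and 1.73 and 2.15 in wild-type and knockout chronic DSS (n = 5 each). It averaged 11.65 ± 0.21 (SD, n = 3) in wild-type acute controls and 7.41 ± 0.60 (SD, n = 5) in wild-type acute DSS, while knockout acute DSS arrays ranged from 6.94 to 10.80. Casp14 averaged 10.14 ± 0.29 (SD, n = 5) in wild-type chronic controls and 8.04 ± 1.02 (SD, n = 5) in knockout chronic controls, and Plet1 7.42 ± 0.49 and 10.19 ± 1.64, so a wide spread was not confined to DSS groups. The labels do not give the position along the colon from which tissue was taken.

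Camk2b, Wdfy1 and Xpnpep2 were higher in knockout in each of the 4 genotype comparisons. Xpnpep2 stood at 2.23, 2.77, 1.60 and 2.07 in acute controls, acute DSS, chronic controls and chronic DSS, Wdfy1 at 0.94, 0.64, 0.92 and 0.76, and Camk2b at 0.64, 0.68, 0.57 and 0.55. With animal series in the model Xpnpep2 in acute controls (1.49, adjusted p = 0.0645), Wdfy1 in chronic DSS (0.62, adjusted p = 0.0946) and Camk2b in acute controls, chronic controls and chronic DSS (0.48, 0.57 and 0.56, adjusted p = 0.116, 0.0663 and 0.179) did not pass. Within the series that held both genotypes in chronic controls, Xpnpep2 (1.69, adjusted p = 0.126) and Camk2b (0.57, adjusted p = 0.130) did not pass, while Wdfy1 did (0.84, adjusted p = 0.00163). In chronic controls this fit rests on the same differences as the one with series in the model.

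Within knockout acute DSS, the second animal series differed from the plain numbers in 2967 genes, 1323 higher and 1644 lower. Y-linked signal appeared in knockout acute control replicate 2 and knockout acute DSS replicate 4 among 37 arrays.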
